A study of Homo sapiens with 6 samples.

How the data were processed

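Total RNA of PC3 cells was extracted with Trizol, and 100 ng per sample was turned into biotin-labelled single-stranded cDNA with a whole-transcript kit for Affymetrix arrays, per the labels' protocols. Per the submitters' processing notes, the arrays were processed by RMA in Affymetrix Expression Console, with no version given. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set on the log2 scale. The deposited log2 values, however, lie around 0: the medians of the 6 arrays are -0.00898, -0.0104 and -0.0303 for miR-34c replicates 1 to 3 and -0.000421, 0.0615 and -0.0175 for scramble replicates 1 to 3, and the values run from -2.86 to 3.77. So a reference value was subtracted from each probe set, in a step the sources used here do not describe. In 5622 of 28868 probe sets (19.5%) 2 arrays hold values of equal size and opposite sign (to within 5e-06), as the subtraction of a median over an even number of arrays gives. In 29.8% all 6 arrays lie on one side of 0, so the reference was not the median of these 6 arrays. A reference common to all 6 arrays cancels in the difference between groups, but the brightness of a probe set is unknown: levels of different genes cannot be compared, genes that the cells do not express cannot be set aside, and a value near 0 says nothing about abundance. The log base is taken as 2 because RMA gives log2 values. The genome build is not given in the sources used here, and no coordinates are printed.

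The 6 arrays fall into 2 groups of 3 by their titles, which also number them 1 to 3. No arrays held identical values. Of the probe sets, 19309 are paired with 1 gene symbol in GEO's platform annotation, 1752 with several and 7807 with none, and only those with 1 symbol were named and tested. Their symbols were checked through the Entrez ID against the RefSeq gene table of GRCh38.p14, where 19278 were found and none changed. For the 685 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was used. That rule was meant to pick the brightest, which centred values do not show, and the mean of the probe sets was tried as an alternative.

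The test was limma (version 3.58.1 in R 4.3.3): lmFit on the deposited log2 values of the 18376 genes with the group as the only term, and eBayes with a trend of the variance on the mean, with Benjamini-Hochberg adjustment and a threshold of 0.05. The trend was planned for values that carry the brightness, and the fit without it is among the alternatives. In total 5361 genes had an unadjusted p under 0.05. The fit was tested on simulated data for this comparison over 18376 genes with the spread of the real arrays and 200 changed genes. The noise was drawn independently for each gene and array, so genes were not correlated and arrays did not differ in quality. Far fewer genes were changed than the 2881 called in the real data, so the recovery may differ there. The fit recovered 74.6% of the 67 genes changed 1.5-fold, 92.5% of the 67 changed 2-fold and 98.5% of the 66 changed 4-fold, and called 11 of 18176 unchanged genes. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01 over the 28 lists with at least 5 measured members, adjusted over the lists. Of the lists 13 were called, 10 upward and 3 downward. With an estimated correlation none was called, and the smallest adjusted p was 0.188. The estimates for the called lists ran from 0.044 (microRNA machinery) to 0.552 (heat shock), all above the preset. By fry, which asks whether the genes of a list move on balance one way, 13 were called, 11 of them the same. The lists cover published targets of miR-34 and miR-205, cell cycle, replication, mitosis, histones, p53 targets, the BCL2 family, epithelial and mesenchymal markers, receptor tyrosine kinases, the Notch and Wnt pathways, interferon and NF-kappaB responses, stress responses, metabolism, ribosomal proteins, the microRNA machinery, the microRNA loci, and markers of prostate luminal, neuroendocrine, fibroblast, leukocyte and endothelial cells. All but 2 of the listed symbols were matched, older ones through the synonyms of the gene table.

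Genes are named by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, of the miR-34 targets the 8 with the smallest adjusted p, always with MET, of the miR-205 targets the 4 with the smallest, up to 3 of every other list, and the named microRNA loci. Genes outside the rule are marked as chosen after their values were seen. Values are log2 changes with their standard errors or folds, which are 2 to the power of the log2 change. Other settings chosen in advance were the replicate number as a block, eBayes without trend or with a robust prior, centring or quantile-normalizing the arrays again, array weights, the mean of a gene's probe sets, all probe sets whether named or not, other set tests, and leaving out each array. Protein-coding genes alone, and the fit without the array of lowest weight in each group, were added after the data were seen. The planned filters on dim probe sets could not be run on centred values, and the planned tests of microRNA seed sites in 3' UTRs were not run, because no transcript sequence was used here.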

Results

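Messenger RNA was measured on 6 whole-transcript arrays of PC3 cells, an androgen-independent human prostate cancer line. In 3 samples miR-34c, a member of the p53-induced miR-34 family, was expressed ectopically, and in 3 a scramble mimic was used as the control. The sample labels name miR-34c, and so does the series title, which puts the aim as finding the targets of miR-34c, whereas the design text of the series names miR-205. The groups are given here as the sample labels give them, and published targets of both microRNAs were examined. Across 28868 probe sets the correlation between arrays of the same group lay between 0.77 and 0.88, and between arrays of different groups between 0.56 and 0.70. After 1 probe set was kept per gene, 18376 named genes were tested. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, and their number limits the precision.

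The miR-34c arrays differed from the scramble arrays most in genes of the interferon response, which made up most of the largest rises. MX2 and MX1, antiviral GTPases, were 25.2-fold and 14.1-fold higher (log2 changes of 4.66 ± 0.13 and 3.82 ± 0.14, SE, n = 3 per group). SAMD9L and SAMD9, antiviral factors that act on translation, were 15.1-fold and 12.5-fold higher, and IFIT1, which binds foreign RNA, was 14.8-fold higher. OAS1, OAS2 and OAS3, the sensors of double-stranded RNA that activate RNase L, were 12.3-fold, 11.6-fold and 10.8-fold higher, and IFI44 was 10.4-fold higher. CLTRN, which encodes collectrin, rose by 3.57 ± 0.11 (SE) on the log2 scale, or 11.9-fold. The largest limma adjusted p among these 10 genes was 1.2e-06.

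The largest falls were smaller in size. MIR125B1, MIR100 and MIRLET7A2, the loci of the microRNAs miR-125b, miR-100 and let-7a, fell to 0.295, 0.318 and 0.417 of the scramble level, and BLID, which lies among them, fell to 0.38 of it, a call that was lost when only protein-coding genes were fitted (adjusted p = 0.402), with the same log2 change of -1.40 in both fits. These 4 are neighbours that overlap or lie in one annotated gene, so their falls may not be separate changes. IGFBP5, a secreted binding protein of insulin-like growth factors, fell by 1.56 ± 0.14 (SE) on the log2 scale, and RAB3B, a small GTPase of vesicle traffic, fell by 1.36 ± 0.12. The pseudogene SERTAD4BP fell by 1.29 ± 0.16. MMP1, interstitial collagenase, and ADAM19, a membrane metalloproteinase, fell to 0.435 and 0.442 of the scramble level, and CDC23, a subunit of the anaphase-promoting complex, fell to 0.442 of it. The limma adjusted p of these 10 falls lay at or below 0.00107, the value of MIR125B1.

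**Figure D1:**
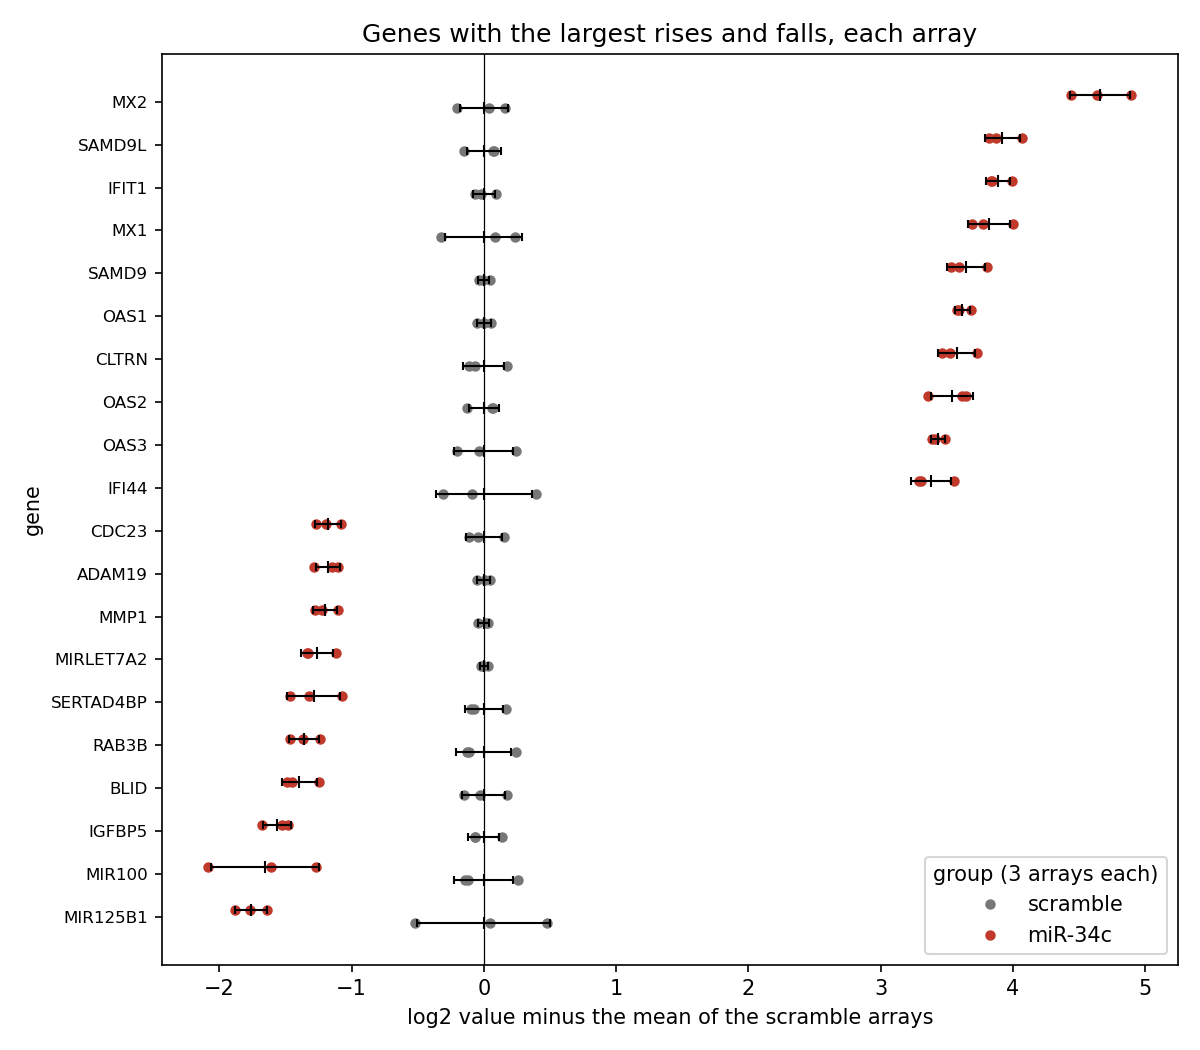
Log2 values of the 10 genes with the largest rises and the 10 with the largest falls on each of the 6 arrays, drawn relative to the mean of the 3 scramble arrays of that gene (grey, scramble; red, miR-34c; bars, mean ± SD, n = 3). Within each gene the 3 miR-34c arrays lie apart from the 3 scramble arrays, because the rule that chose the genes required it. The average differences run from 4.66 above for MX2 to 1.76 below for MIR125B1.

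In all, 2881 genes differed between the groups at a Benjamini-Hochberg adjusted p under 0.05 in limma, 1409 higher and 1472 lower with miR-34c. Of these, 433 were at least 1.5-fold higher and 271 at least 1.5-fold lower. Rises of at least 4-fold were found in 37 genes, 26 of them among the interferon-stimulated genes of a list fixed before the data were examined, and falls of that size in 0. The count was 1683 without miR-34c replicate 2 (841 higher, 842 lower) and 1655 without miR-34c replicate 3 (897 higher, 758 lower), whereas the count of changes of at least 1.5-fold lay between 674 and 863 when any 1 array was left out.

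Of the 39 measured interferon-stimulated genes, 34 rose and none fell, with a median log2 change of 2.36. OAS1 had the smallest adjusted p of all genes (6.61e-09, limma). The count was 34 when any 1 array was left out, and 35 rose when adjusted over the list alone. The 5 members that did not pass, named after their values were seen, were the interferon genes IFNB1 (log2 change 0.17, adjusted p = 0.36) and IFNL1 (0.05, adjusted p = 0.755), the chemokines CXCL10 (0.16) and CXCL11 (0.17), and ISG20 (0.25). The list was higher than other genes by camera (adjusted p = 1.11e-58 with a preset correlation, adjusted p = 0.188 with an estimated correlation). Of the 14 measured leukocyte markers, none passed the test over all genes or adjusted over the list alone (median log2 change -0.07).

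Inflammatory genes rose as well. Of 25 measured NF-kappaB targets and inflammatory cytokines 10 rose and none fell, or 12 adjusted over the list alone. IL32, a proinflammatory cytokine, was 2.93-fold higher, IL6 was 2.76-fold higher, and CXCL8, the neutrophil chemokine, was 2.30-fold higher (limma adjusted p at or below 0.000415, the value of CXCL8). The median of the list was a log2 change of 0.18, and it stood above other genes by camera (adjusted p = 3.11e-08, adjusted p = 0.372 with an estimated correlation).

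**Figure D2:**
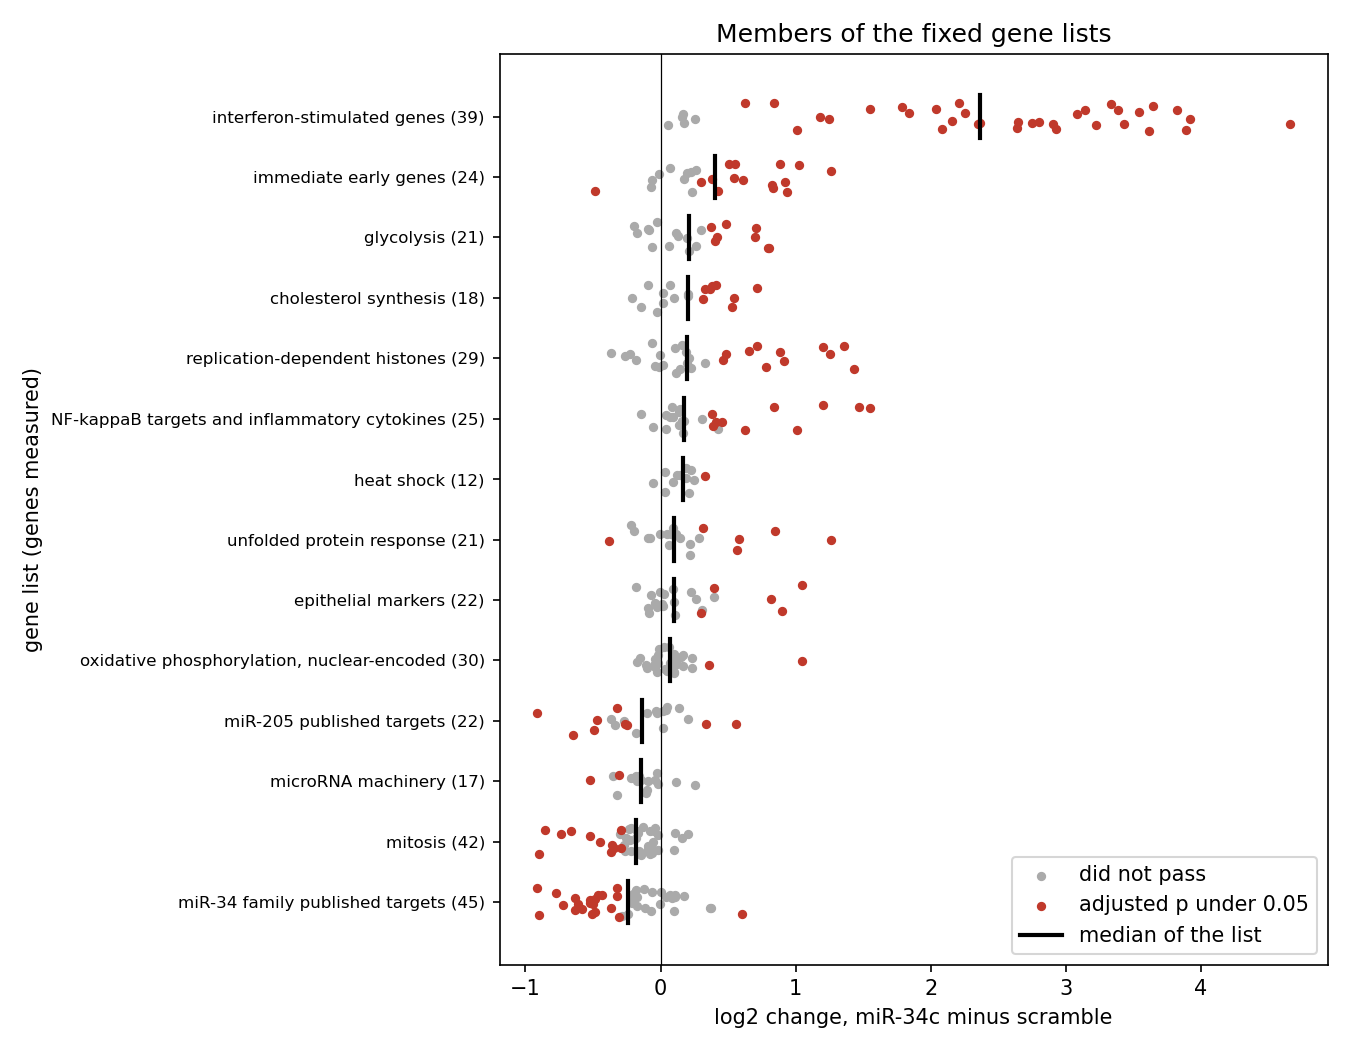
Log2 change, miR-34c minus scramble, of each measured member of the 13 lists called by camera and of the published miR-205 targets (red, limma adjusted p under 0.05; grey, did not pass; black bar, median). The interferon-stimulated genes lie farthest from 0, with a median of 2.36, and the published miR-34 targets have the lowest median, -0.24.

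Published targets of the miR-34 family were lower with miR-34c. Of 45 measured targets 21 fell, 1 rose and 23 did not pass, and adjusted over the list alone 21 fell and 3 rose. MET, the receptor of hepatocyte growth factor, fell to 0.703 of the scramble level (log2 change -0.51 ± 0.08, SE, limma adjusted p = 0.00194). The smallest adjusted p-values of the list belonged to SYT1, synaptotagmin-1, at 0.535 of the scramble level, FUT8, a fucosyltransferase, at 0.643, and AXL, a receptor tyrosine kinase, at 0.586. RRAS, NOTCH2, MTA2 and FOSL1 fell to between 0.654 (NOTCH2) and 0.716 (FOSL1) of the scramble level. SNAI1, a transcription factor that represses epithelial genes, was the member that rose, 1.52-fold, and 2 rose without miR-34c replicate 1 and 3 without scramble replicate 1. MYC (log2 change 0.07), BCL2 (-0.12), CCND1 (-0.21) and SIRT1 (-0.00116), chosen after their values were seen, did not pass. The list stood below other genes by camera (adjusted p = 4.13e-06, adjusted p = 0.372 with an estimated correlation), and its median log2 change was -0.24.

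Of 22 measured published targets of miR-205, 7 fell, 2 rose and 13 did not pass, and 9 fell and 2 rose when adjusted over the list alone. E2F5, an E2F transcription factor that stands on the lists of both microRNAs, fell by 0.91 ± 0.16 (SE) on the log2 scale, and the kinase SRC, the laminin subunit LAMC1 and CHN1 fell to 0.638, 0.721 and 0.711 of the scramble level. The members that rose, named after their values were seen, were the kinase LYN (log2 change 0.56) and VEGFA (0.34). ZEB1 and ERBB3, chosen likewise, had log2 changes of 0.02 and 0.04 and did not pass. The list did not pass camera (adjusted p = 0.12, median log2 change -0.14). The count of falls was 4 without each of miR-34c replicates 2 and 3 and scramble replicates 1 and 2, and that of rises 0 without miR-34c replicate 2 and 1 without miR-34c replicate 3.

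Genes of mitosis were lower, with 11 of 42 measured members fallen, 12 adjusted over the list alone, and none risen. TOP2A, topoisomerase II alpha, FOXM1, the transcription factor of the G2/M programme, and the mitotic kinase PLK1 fell to 0.602, 0.553 and 0.536 of the scramble level (limma adjusted p at or below 0.000284, the value of PLK1). The list stood below other genes by camera (adjusted p = 6.31e-05, adjusted p = 0.372 with an estimated correlation), and 6 members fell without miR-34c replicate 2 and 7 without scramble replicate 2. Of 27 G1/S cyclins, kinases and E2F factors 5 fell and 1 rose. SKP2, a ubiquitin ligase subunit that marks p27 for degradation, fell to 0.599 and CDK4 to 0.707 of the scramble level, and E2F7, a repressor E2F, was the member that rose, 1.45-fold. Adjusted over the list alone, 5 fell and 2 rose, and the list did not pass camera (adjusted p = 0.613). Its median log2 change was -0.01, or 0.01 with each array centred on its median, and 2 rose without scramble replicate 1 and 3 without scramble replicate 2.

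Genes of DNA replication went both ways. Of 45 members 4 rose and 2 fell, with the same counts adjusted over the list alone. MCM3, a subunit of the replicative helicase, and GINS1 fell to 0.672 and 0.615 of the scramble level, and POLA2, a subunit of DNA polymerase alpha, was 1.41-fold higher. The camera adjusted p was 0.323, and 1 member rose without miR-34c replicate 1, miR-34c replicate 2, miR-34c replicate 3 or scramble replicate 1, and 2 rose with the replicate number as a block. Replication-dependent histones were higher, with 11 of 29 members risen and none fallen, or 12 risen and 1 fallen adjusted over the list alone. H3C3, H3C10 and H3C2, genes of histone H3, were 2.70-fold, 2.57-fold and 2.30-fold higher. Genes of one histone class are similar in sequence, and an array may not keep all their signals apart, so each value is uncertain as that of a single gene. Without scramble replicate 1, 1 member fell. The histone list passed camera (adjusted p = 1.15e-05, adjusted p = 0.372 with an estimated correlation).

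Of 26 measured p53 target genes 7 rose and 3 fell, or 8 and 5 adjusted over the list alone. PMAIP1, which encodes the proapoptotic protein NOXA, was 1.68-fold higher, PHLDA3, an inhibitor of AKT, 1.47-fold higher, and PLK2, a stress-responsive kinase, 1.43-fold higher. The p53 list did not pass camera (adjusted p = 0.12), and 3 members rose without miR-34c replicate 2 and 4 without each of miR-34c replicate 3 and scramble replicate 1. The count of falls was 1 without each of the miR-34c replicates and scramble replicate 1. Of 15 members of the BCL2 family, PMAIP1 and BCL2L11, which encodes the proapoptotic protein BIM, rose, BCL2L11 by 1.36-fold, and none fell, with the same counts adjusted over the list alone. BCL2A1 had a log2 change of -0.38 ± 0.16 (SE) and did not pass, but passed without scramble replicate 3 (-0.55, adjusted p = 0.0438). The BCL2 family list did not pass camera (adjusted p = 0.187).

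Epithelial markers were higher in part, with 5 of 22 risen and none fallen, or 6 risen adjusted over the list alone. KRT7, keratin 7, was 2.07-fold higher, DSP, desmoplakin, 1.86-fold higher, and ELF3, an epithelial transcription factor, 1.76-fold higher. The list passed camera (adjusted p = 0.00379, adjusted p = 0.429 with an estimated correlation), and 3 members rose without miR-34c replicate 3 or scramble replicate 3. Of 19 mesenchymal markers 5 fell and 2 rose, or 7 and 3 adjusted over the list alone. TNC, the matrix protein tenascin-C, fell to 0.552 of the scramble level, while SNAI1 rose. The mesenchymal list did not pass camera (adjusted p = 0.165).

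Among 22 receptor tyrosine kinases 5 fell and 1 rose, with the same counts adjusted over the list alone. FGFR1, a receptor of fibroblast growth factors, fell to 0.598 of the scramble level, beside AXL and MET, and the list did not pass camera (adjusted p = 0.127). The member that rose was MST1R, named after its value was seen, and the count of rises was 0 without each array but scramble replicate 2. In the Notch pathway 4 of 21 genes fell and 3 rose, the same adjusted over the list alone. HEY1, a target of Notch signalling, and the receptor NOTCH2 fell to 0.702 and 0.654 of the scramble level, and the coactivator MAML2 was 1.34-fold higher (camera adjusted p = 0.536). In the Wnt/beta-catenin pathway 3 of 27 genes fell and 3 rose, or 4 and 3 adjusted over the list alone. LGR4, a receptor of R-spondins, fell to 0.567, FZD4, a Frizzled receptor, fell to 0.677, and DVL3, a Dishevelled protein, was 1.44-fold higher (camera adjusted p = 0.535).

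Immediate early genes were higher with miR-34c. Of 24 members 14 rose and 1 fell, or 16 and 1 adjusted over the list alone. ATF3 was 2.39-fold, the phosphatase gene DUSP1 2.03-fold and JUNB 1.91-fold higher, and FOSL1 was the member that fell. The list passed camera (adjusted p = 5.75e-09, adjusted p = 0.372 with an estimated correlation), with a median log2 change of 0.40. In the unfolded protein response 5 of 21 genes rose and 1 fell, or 7 and 2 adjusted over the list alone. ATF3 is on this list too, DDIT3, which encodes CHOP, was 1.80-fold higher and CRELD2, a resident protein of the endoplasmic reticulum, rose by 0.58 on the log2 scale. XBP1, named after its value was seen, fell by 0.38, and the count of falls was 0 without miR-34c replicate 2. The list passed camera (adjusted p = 0.00379, adjusted p = 0.429 with an estimated correlation). Of 12 heat shock genes HSPB1 rose, 1.25-fold, and no member passed adjusted over the list alone. HSPB1 did not pass with the replicate number as a block (adjusted p = 0.0558), nor without miR-34c replicate 2 (0.137), miR-34c replicate 3 (0.119), scramble replicate 1 (0.081) or scramble replicate 3 (0.0977). DNAJA1 and HSPE1 had log2 changes of 0.22 and 0.25 and did not pass. DNAJA1 passed with each array centred on its median (adjusted p = 0.033), with quantile normalization again (0.0304) and with array weights (0.0333), and HSPE1 with array weights (0.0497). Heat shock genes as a list passed camera (adjusted p = 0.0145, adjusted p = 0.619 with an estimated correlation), but not fry (adjusted p = 0.0932).

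In glycolysis 8 of 21 genes rose and none fell, or 12 and 1 adjusted over the list alone. PFKL, the liver form of phosphofructokinase, ALDOC, aldolase C, and ENO2, enolase 2, were 1.73-fold, 1.74-fold and 1.64-fold higher. GAPDH (log2 change -0.09) and LDHA (-0.06), chosen after their values were seen, did not pass. The list passed camera (adjusted p = 6.89e-05, adjusted p = 0.372 with an estimated correlation). In cholesterol synthesis 8 of 18 genes rose and none fell, the same adjusted over the list alone. INSIG1, a sterol-regulated inhibitor of SREBP processing, the sterol carrier STARD4 and the isomerase IDI1 were 1.45-fold, 1.64-fold and 1.44-fold higher. The cholesterol list passed camera (adjusted p = 0.000486, adjusted p = 0.372 with an estimated correlation), and 5, 3 and 4 members rose without miR-34c replicate 2, miR-34c replicate 3 and scramble replicate 1.

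Nuclear-encoded genes of oxidative phosphorylation differed little. Of 30 members 2 rose and none fell, the same adjusted over the list alone. NDUFB5, a subunit of complex I, was 2.07-fold higher, NDUFA2 was 1.28-fold higher, and NDUFV2 had a log2 change of 0.23 and did not pass, but passed with quantile normalization again (0.26, adjusted p = 0.0426), which gave 3 rises. NDUFA2 did not pass without miR-34c replicate 1 (adjusted p = 0.0519), miR-34c replicate 2 (0.0689) or scramble replicate 1 (0.0513), each of which left 1 rise. The list passed camera (adjusted p = 0.0478, adjusted p = 0.487 with an estimated correlation). It did not pass by fry (adjusted p = 0.0681), nor without miR-34c replicate 1 (0.101), miR-34c replicate 2 (0.0647), scramble replicate 1 (0.0902) or scramble replicate 2 (0.0591), and 4 other settings gave 0.0512 to 0.115. Of 35 ribosomal proteins 3 fell and none rose, or 2 adjusted over the list alone. RPL32 fell to 0.602, RPL22 to 0.791 and RPS7 to 0.80 of the scramble level. These genes have many processed pseudogenes, so their values are uncertain, and the other probe set of RPS7 gave a log2 change of -0.08. RPS7 did not pass without each array but scramble replicate 3 (adjusted p from 0.0738 to 0.17) or with the mean of its probe sets (0.134), and 1 member of the list rose without scramble replicate 3. The camera adjusted p was 0.362.

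In the microRNA machinery 2 of 17 genes fell and none rose, or 4 adjusted over the list alone. DICER1, which cuts microRNA precursors, fell to 0.697 and TARBP2, its partner, to 0.807 of the scramble level, and PRKRA had a log2 change of -0.32 ± 0.10 (SE, adjusted p = 0.0521 in limma). The list passed camera (adjusted p = 0.0478), but not with an estimated correlation (adjusted p = 0.372), nor with the replicate number as a block (adjusted p = 0.0566), nor without miR-34c replicate 1 (adjusted p = 0.0962), miR-34c replicate 2 (adjusted p = 0.0647) or scramble replicate 3 (adjusted p = 0.0785). TARBP2 did not pass without miR-34c replicate 1 (adjusted p = 0.0567), miR-34c replicate 3 (0.106) or scramble replicate 3 (0.0604), and PRKRA passed in 5 other settings (0.0288 to 0.0486), among them with each array centred on its median (0.0365). The count of falls was 1 without miR-34c replicate 3 or scramble replicate 3, and 4 with the arrays centred, where 1 member rose. Of the loci of the named microRNAs, MIR34A (log2 change -0.21), BTG4 next to the miR-34b/c locus (-0.16) and MIR34B (-0.13) did not pass. Whether such probe sets would register an introduced microRNA was not tested, so these values do not show whether it was present. The probe sets that cover MIR34C and MIR205 are each paired with more than 1 gene and are not named.

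Of 11 androgen response and prostate luminal genes 3 fell and none rose, the same adjusted over the list alone. HPGD, which breaks down prostaglandins, fell to 0.706, SLC45A3 to 0.774 and HOXB13 to 0.823 of the scramble level (camera adjusted p = 0.127), and 1 member fell without miR-34c replicate 3. HOXB13 passed only without scramble replicate 1 when 1 array was left out (adjusted p from 0.0725 to 0.176 without each of the others) and was lost without the variance trend (0.0586) and with the replicate number as a block (0.0741), and SLC45A3 did not pass without miR-34c replicate 2 (0.0575) or miR-34c replicate 3 (0.0662).

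Markers of other cell types gave few calls, none of them a list call by camera. Of 14 fibroblast markers COL6A3, a collagen VI chain, and PDGFRA fell, to 0.652 and 0.716 of the scramble level, and FBLN1 rose 1.30-fold, or 3 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.5). FBLN1 did not pass without miR-34c replicate 2 (adjusted p = 0.0857), miR-34c replicate 3 (0.085), scramble replicate 1 (0.051) or scramble replicate 3 (0.0505), and 2 members rose without scramble replicate 2. Of 11 endothelial markers PECAM1 fell, by 1.17 ± 0.17 (SE) on the log2 scale, and its other probe set gave a change of -0.30 that did not pass, while EMCN (-0.13) and ERG (-0.13) did not pass. PECAM1 was also the 1 call adjusted over the list alone, and the camera adjusted p was 0.436. Of 9 neuroendocrine markers SYT1 fell and ENO2 rose, the same adjusted over the list alone, NCAM1 had a log2 change of 0.08, and the mean (-0.02), unlike the median (0.02) and the direction of the test, lay below 0 (camera adjusted p = 0.828). Among leukocyte markers FCGR3A (-0.25), MS4A1 (-0.18) and PTPRC (0.16) had the smallest p-values and did not pass (camera adjusted p = 0.536). MS4A1 passed without the array of lowest weight in each group (-0.39, adjusted p = 0.0383), the 1 fall of the list in that setting.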

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

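Neither result below was part of a comparison, and both are given because they lie in probe sets that the named-gene tests do not use. In a fit over all probe sets, 396 of the 7807 probe sets with no gene in the platform annotation passed a limma adjusted p of 0.05, 112 higher and 284 lower with miR-34c, with log2 changes from -1.49 to 2.03. Of the 1752 probe sets paired with several genes 153 passed, 69 higher and 84 lower, with changes from -1.14 to 3.17. In the same fit 12.6% of the probe sets with 1 gene symbol passed, against 5.07% of those with no gene and 8.73% of those with several. The estimated weights of the arrays ran from 0.453 for scramble replicate 2 to 1.78 for miR-34c replicate 3. The series holds only 1 contrast, so no effects could be set against each other.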

How the results depend on the processing

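The alternatives with protein-coding genes alone and without the array of lowest weight in each group (miR-34c replicate 1 and scramble replicate 2) were chosen after seeing the data; the others were planned. No named gene and no list reversed its direction with a call on either side. The count of changed genes was 2675 with the replicate block, 2867 without the variance trend, 2850 with the robust prior, 3276 with arrays centred, 3374 with quantile normalization again, 3517 with array weights, 2918 with the mean of probe sets, 2861 for protein-coding genes, 2976 over all probe sets and 2605 without the 2 arrays of lowest weight, of which 1969 were among the 2881. Leaving out 1 array gave 1655 to 2652 changed genes (841 to 1572 higher, 758 to 1373 lower) and 674 to 863 changed at least 1.5-fold (409 to 530 higher, 236 to 387 lower). Over all probe sets 409 fell at least 1.5-fold, against 271 genes, with more features tested; without miR-34c replicate 3 or replicate 2, 1636 of the 1655 and of the 1683 calls were among the 2881, in fits with fewer arrays. Among the calls 48.9% were higher, 52.4% with arrays centred, 59.3% without scramble replicate 2 and 43.0% without scramble replicate 3; the scalings moved the median of all genes from -0.03 to -0.01 at most. The number of lists called was 13, between 11 and 13 when 1 array was left out, 11 with the replicate block, and 0 with an estimated correlation. There the interferon list had a camera adjusted p of 0.188 and the miR-34 targets of 0.372. Their estimated correlations were 0.342 and 0.140, against the preset 0.01, and camera raises the variance of a list's statistic with the correlation. The p-values with the preset therefore rest on a correlation below the estimates for these lists. The correlation is not the only difference, since p also rose where the estimate lay below the preset. For the androgen response list (estimate -0.0036) the unadjusted camera p went from 0.0727 with the preset to 0.133 with the estimate. The miR-34 list had adjusted p between 5.24e-07 and 0.000119 without 1 array, the interferon list between 5.34e-65 and 2.72e-45, and the miR-205 list between 0.0717 and 0.163. By fry the androgen response and fibroblast lists were also called (adjusted p = 0.0199 each). Of 88 named genes that passed, 80 did so in the same direction under every alternative over genes that included them (the fit of protein-coding genes leaves out MIR125B1, MIR100, MIRLET7A2 and SERTAD4BP); the others were HOXB13, RPS7, HSPB1, TARBP2, NDUFA2, SLC45A3, FBLN1, and BLID, which did not pass among protein-coding genes alone (adjusted p = 0.402) at an equal log2 change of -1.40, so that the modelled variance and not the change differed; why it differed was not tested. Of the 14 named genes that did not pass, PRKRA, DNAJA1, HSPE1, NDUFV2, MS4A1 and BCL2A1 passed under at least 1 alternative. The titles' numbers showed no clear pairing of the arrays. Same-numbered arrays had correlations of -0.01, 0.12 and -0.09 after group means were removed, and 2 of 6 correlated best with their own number. With 3 arrays per group this check is too weak to exclude a pairing. The replicate block ended the calls of HSPB1, HOXB13, the microRNA machinery and oxidative phosphorylation. Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave as many as 2881 genes, 704 genes at least 1.5-fold or 13 lists; the highest of the others gave 0, 0 and 6, and 10 splits are too few for a share under 0.05. The filters on dim probe sets and the seed site and heptamer tests were not run.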

Other observations

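The gene groups of the first 2 paragraphs and the tests of array scaling, leukocytes, a second mimic and the miR-205 label were chosen after results were seen, whereas the tests of neighbouring genes were set before theirs. Of 13 measured genes of antigen presentation by MHC class I, 11 rose with miR-34c and 2 did not pass. TAP1, a subunit of the peptide transporter, was 3.27-fold higher, the immunoproteasome subunits PSMB9 and PSMB8 were 2.58-fold and 2.14-fold higher, and B2M, the light chain of MHC class I, was 2.29-fold higher, with 11 rises under each scaling of the arrays, while TAPBP (log2 change -0.01) and PSMB10 (0.13) did not pass.

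Of 16 measured genes of the protocadherin beta cluster 10 fell, none rose and 6 did not pass, with PCDHB14 and PCDHB10 at 0.489 and 0.498 of the scramble level, and of 23 bitter taste receptor genes 10 fell, none rose and 13 did not pass, with TAS2R50 at 0.525 (9 in each with the arrays quantile-normalized again). Both families hold similar sequences, so single values are uncertain, and neither was tested for enrichment against other genes. Over classes of genes, falls were not more frequent among microRNA loci (6.36% of 173) than among protein-coding genes (8.15% of 16863), and rises made up 1.16% against 8.10%. Rises also made up 2.85% of 631 long noncoding RNAs and 2.05% of 391 transcribed pseudogenes, of which 6.50% and 6.65% fell, 5.71% of 175 small nucleolar RNAs, of which 6.29% fell, and 0 of 63 other pseudogenes, of which 3 fell. Differences between classes were not tested.

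The rise of the interferon-stimulated genes was the largest pattern in these data. Array scaling as its cause was examined by centring each array on its median, after which the list's median log2 change was 2.38. Centring moved the median of all genes only from -0.034 to -0.017. It could therefore hardly have changed the list's median, and it decides nothing about other kinds of scaling. The differences in array level were far smaller than the rise. With quantile normalization again the list's median was 2.26. Leukocytes in the miR-34c cultures are argued against by their markers, whose median log2 change was -0.07 and none of which passed. PTPRC had a log2 change of 0.16 and LYZ of 0.00118. The 95% bootstrap interval of that median ran from -0.11 to -0.0043. The median is taken over genes, which are not replicates, so the interval does not measure the spread between arrays. It is not read as a fall, since the list did not pass camera (adjusted p = 0.536). PC3 is a cell line, so leukocytes were unlikely beforehand and the marker test adds little. A response to the transfected RNA itself, rather than to lost miR-34c targets, stays open and cannot be told apart from one to miR-34c, since the series has 0 groups with a second mimic or without a mimic. The list's median deposited value was 1.06 in the miR-34c and -1.37 in the scramble arrays around a reference that is not given, so which group departed from untransfected cells is open too.

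The sample labels name miR-34c and the design text miR-205, which raises the question whether the arrays hold miR-205 and not miR-34c. Of 44 published miR-34 targets outside the miR-205 list 20 fell (45.5%), against 40 of 559 genes of the other lists (7.16%, two-sided Fisher's exact p = 1.17e-10), which argues against miR-205 alone as the explanation. Of 21 miR-205 targets outside the miR-34 list 6 fell (28.6%, two-sided Fisher's exact p = 0.00391), and the difference between the target lists did not pass (two-sided Fisher's exact p = 0.28), so these lists do not exclude an effect on miR-205 targets. These tests take genes as independent, which they are not. Biology shared by the lists, such as growth factor signalling, was not tested.

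Genes that fell at least 1.5-fold tended to lie next to each other. Of 270 such genes placed by the RefSeq table of GRCh38.p14, 19 adjacent pairs both fell, against 3.95 on average in 10000 random placements (permutation p = 1e-04, the smallest these can give), which argues against chance placement. Without pairs that share a symbol stem 12 pairs were left (permutation p = 6e-04), and without pairs that overlap or lie in one annotated gene 9 (permutation p = 0.0074). Neither paralogues nor a shared host gene thus accounts for all of it alone. Without both kinds 7 were left against 3.09 (permutation p = 0.035), where the 95th percentile of the placements was 6. PECAM1 with MILR1 is among these 7 and rests on the probe set used for PECAM1. The other PECAM1 probe set gave a log2 change of -0.30 and did not pass, so this last result is weak. The pairs include MIR125B1, BLID, MIRLET7A2 and MIR100 in a row, MIR31HG, IFNE, MIR31 and MTAP in a row, and PECAM1 with MILR1. A candidate explanation is that long primary transcripts over such loci were lower, which was not tested.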
